A study of Danio rerio with 33 samples.

How the data were processed

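Whole zebrafish embryos were exposed for 24 h, from 96 to 120 hours after fertilisation, and RNA was taken from pools of 10 embryos, per the labels' protocols. The exposures were organic extracts of air particle filters taken with dichloromethane and methanol and held in methanol. Libraries were made from poly-A RNA with a stranded kit and sequenced as read pairs. The 33 libraries fall into 6 vehicle libraries, 3 of mock filter extract, 9 of harbour filters, 9 of traffic road filters, 3 of airport filters and 3 of a subway filter. Each library number in the labels starts with 35, 37 or 38, called the library series here. Series 35 holds 15 libraries, series 37 holds 14 and series 38 holds 4. Each library is 1 embryo pool, and pools exposed to the extract of 1 filter were taken as repeats of that extract, not of the sampled air, from the replicate numbers in the labels. A further number in the titles differs between series and is not explained in the sources used here, so an equal dose in all pools of a filter is an assumption.

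The deposited gene table holds raw read counts per gene and library, whole numbers with no normalisation, for 25432 protein-coding genes. The deposited quality table gives percent of uniquely mapped, unmapped and duplicate reads per library, with the number of read pairs and the mean insert size, per the file headers. CASAVA, BWA and the genome build GRCz11 are named in the submitters' processing notes, without versions. The counting program, its strand setting and the annotation release are not given in the sources used here, so counts of near-identical genes (the fthl ferritins, jac lectins, keratins, elastases and globins) are uncertain as single genes where counting could split their reads. Symbols came from the gene table for 17766 genes and from a separate table of gene IDs for 5860; 1806 genes had no symbol. No duplicated gene ID and no column without a library was found. Among the 45 pairs of libraries within 1 control group or 1 filter, the chi-square per degree of freedom lay between 4.56 and 87.03, so no library of these pairs was a copy or a split of the other.

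Library totals ran from 18448718 to 51854033 counts. Uniquely mapped reads made up 71.66 to 77.08 percent in series 35, 78.88 to 79.5 percent in series 37 and 78.74 to 79.31 percent in series 38. Unmapped reads made up 1.43 to 1.67 percent in series 35 and 0.58 to 0.73 percent in series 37. The quality table places series 35 in a first sequencing round and series 37 and 38 in a second.

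Genes with enough counts were kept with filterByExpr, which left 22124. Counts were scaled by TMM and fitted with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with 1 coefficient per site and the library series as covariate. A second fit had 1 coefficient per filter. All 33 libraries entered both of these fits, so that groups shared the estimate of spread. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Log2 fold changes are given with their standard error (SE). Expression per library is given as CPM (edgeR), scaled by TMM, with the standard deviation (SD). Log2 CPM had a prior count of 2.

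The comparisons, the tests, 33 gene lists and the rule for named genes were chosen before the data were examined. Lists held pathways, organ markers and housekeeping groups. For the lists it names, the text gives the members that passed over all genes tested and, for most comparisons, those that passed when p-values were adjusted over the list alone. Lists were tested as sets with camera in limma 3.58.1 on voom values, with the correlation between members estimated from the data and adjustment over the lists of a comparison. A preset correlation of 0.01 was the alternative. Named genes are every measured member of the list of aryl hydrocarbon receptor (AhR) targets and, in each comparison, up to 10 genes per direction with the largest change among those past the threshold, with a mean log2 CPM of at least 1 and the same sign for every filter (for mock filter and subway, in every library). Up to 4 members per list with the smallest p were added, along with any passing member of a list whose set test passed. Genes with provisional names were left out.

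Harbour and road share the vehicle libraries, so their overlap was set beside 20 simulations of unchanged groups, beside the overlap of independent lists, and beside a split of the vehicle libraries. Harbour filters 36 and 38 carry the same replicate numbers 1 to 4. Deviations of same-numbered libraries from their filter means correlated at 0.449, 0.37, 0.218 and 0.239 across genes, each above 0.1, so the numbers were taken to pair these libraries. The pairing comes from this check and not from a shared batch named in the labels, and number 4 joins a series 38 library with a series 37 library. Number 1 is the series 35 pool in both filters and series was not removed, so series can give part of these correlations. A replicate block was also run where the check did not hold. Each fit with a replicate block held only the compared libraries that share replicate numbers. A smaller count there can come from fewer libraries as well as from the pairing. Same-numbered libraries of filters 26 and 28 correlated at 0.2, 0.062, 0.161 and 0.059, and those of mock filter and vehicle at 0.17, -0.236 and 0.282.

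The tests were run on simulated counts with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold among 22124. At 2-fold, 86.6 percent were recovered for harbour, 92.5 percent for road, 68.7 percent for airport, 43.3 percent for subway and 77.6 percent for mock filter. At 4-fold the recovered shares were 100, 100, 98.5, 84.8 and 93.9 percent in the same order. The comparison of harbour with road recovered 98.5 percent at 2-fold and 76.1 percent at 1.5-fold. False calls numbered 0 to 18 per comparison. The simulated pools were drawn independently around a shared mean per gene, with no shift by series or filter, and genes of low expression were not changed. Real pools of a filter resemble each other (correlation 0.284 in limma voom). These shares can therefore overstate what a comparison of sites recovers, harbour against road included.

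Alternatives were the size factors of DESeq2, the test of DESeq2 1.42.0, no filter on low counts, a minimum log2 fold change of 1, fits of the compared groups alone, no series covariate, vehicle and mock filter pooled as control, the equally weighted mean of the filters, limma voom with the filter as a random block (correlation 0.284), a replicate block, each filter, series and library left out or taken alone. Figures were drawn with matplotlib 3.10.9. In the random block fit each control library was its own block, whatever its title number. The airport season was not tested, since the warm season has 1 library.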

Results

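RNA of whole zebrafish embryos was measured by sequencing after 24 h in extracts of particles from the air of 4 kinds of site. Harbour, traffic road and airport filters came from Barcelona and the subway filter from Valencia, and mock filter extract and the vehicle methanol served as controls. The titles of mock filter 1, 2 and 3 carry the numbers 2, 3 and 3, so these libraries may come from more than 1 mock filter. Vehicle 4 to 6 share the title number 11. Vehicle had 6 libraries with 18448718, 23696885, 19933579, 20206672, 27834671 and 30548926 counts, and mock filter had 3 with 23763328, 20975321 and 23527829. Harbour had 9 libraries of filters 32, 36 and 38 (1, 4 and 4 pools) with 22568653, 18718020, 26727365, 23815527, 19454977, 20496951, 25443727, 26612129 and 27791534 counts. Road had 9 libraries of filters 26, 28 and 30 (4, 4 and 1 pools) with 22384372, 32862446, 27134510, 32588325, 30700810, 33450621, 37020687, 27610181 and 21016846. Airport had 1 pool each of filters 44 and 48 from the cold season and of filter 54 from the warm season, with 18744571, 19227737 and 51854033. Subway had 3 pools of filter 80 with 24369748, 24983683 and 23586397. Harbour and road filters came from the cold season.

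The first principal component held 21.7% of the variance of log2 CPM and the second 14.7%. On the first, the airport libraries scored 42.3 to 72.6, and the series 37 pools of harbour filter 38 and road filter 26 scored 22.7 to 40.5. Vehicle libraries scored -36.3 to -7.7. Vehicle 3 and mock filter 2 and 3 stood apart on the second component with scores of 50.6 to 59.4. In these 3 libraries mxc, an interferon-induced antiviral GTPase, reached 80.7, 58.3 and 63.4 CPM, while vehicle libraries other than vehicle 3 had 1.04 to 1.49 CPM.

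**Figure D1:**
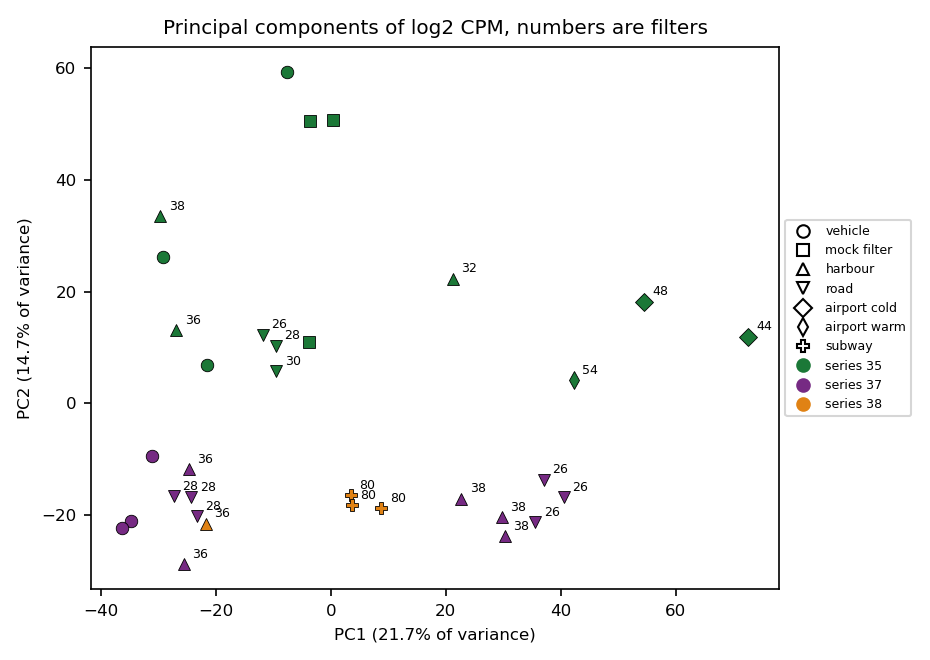
Scores of the 33 libraries on the first (x axis, 21.7% of variance) and second (y axis, 14.7%) principal components of log2 CPM, with shape for the group, colour for the library series and the filter number beside each point. The 3 airport libraries score 42.3 to 72.6 on the first component, and vehicle 3 with mock filter 2 and 3 scores 50.6 to 59.4 on the second.

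The mock filter comparison measured what the filter and its extraction add to the vehicle. 3 genes rose and 0 fell in mock filter (n = 3) against vehicle (n = 6). fthl28 (ENSDARG00000076221), a ferritin heavy chain gene of iron storage, rose by 1.98 ± 0.30 in log2 (SE, adjusted p = 0.00183 in edgeR), from 26.6 ± 15.4 CPM in vehicle to 119 ± 6.53 CPM (SD). SLC30A8, a zinc transporter, rose by 1.56 ± 0.22, and manba, a lysosomal mannosidase, by 0.79 ± 0.12. Of 15 AhR targets 0 passed, and 0 passed when adjusted over the list alone. Unadjusted p was under 0.05 for 3022 genes, and DESeq2 called 98 genes. Without vehicle 3, mock filter 2 and mock filter 3, a choice made after the data were seen, mock filter has 1 library, so no calls are given for that fit. fthl28 was at 127 CPM in mock filter 1 and at 16.5 to 55.1 CPM in the vehicle libraries other than vehicle 3. In a fit of mock filter and vehicle alone 0 genes passed, and without vehicle 3, mock filter 1 or mock filter 3 the count was 1047, 22 or 5.

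Harbour extracts raised the genes that answer to the AhR, the receptor of polycyclic aromatic hydrocarbons and dioxins. ahrra (ENSDARG00000099702), the AhR repressor, rose by 3.04 ± 0.34 in log2 (SE, adjusted p = 9.39e-06 in edgeR), which is 8.22-fold. cyp1a (ENSDARG00000098315), the monooxygenase commonly used as a marker of AhR activity, rose by 1.78 ± 0.26 (adjusted p = 0.000244). Its expression was 113 ± 69 CPM in harbour (SD, n = 9), 33.5 ± 4.52 CPM in vehicle (n = 6) and 34.2 ± 2.46 CPM in mock filter (n = 3). The related P450 genes cyp1b1, cyp1c1 and cyp1c2 rose by 1.72 ± 0.20, 1.1 ± 0.11 and 0.99 ± 0.17. Smaller rises were found for the sulfotransferase sult6b1 (0.48 ± 0.10) and for ahr2, the main AhR of zebrafish (0.29 ± 0.06). In all, 7 of the 15 AhR targets rose, 0 fell and 8 did not pass; adjusted over the list alone, 9 were higher and 1 lower. The list passed as a set (adjusted p = 0.00436 with an estimated correlation).

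In the 9 harbour pools, genes of metal handling rose as well: 6 of 14 members rose and 0 fell, with 6 higher and 1 lower when adjusted over the list alone, and the set passed (adjusted p = 0.0136 with an estimated correlation). The ferritin heavy chain genes fthl28 and fthl31 rose by 2.05 ± 0.25 and 1.64 ± 0.20, and fthl29, outside the list, by 2.15 ± 0.30. mt2, a metallothionein that binds zinc and copper, rose by 0.91 ± 0.16, and slc30a1a, a zinc exporter, by 0.43 ± 0.08. The mean of this list also lay above vehicle in mock filter 1, 2 and 3, by 0.51, 0.38 and 0.3 in log2. The set test against vehicle thus does not part harbour air from the filter and its extraction. The rise of fthl28 was not particular to the harbour air, since fthl28 also rose in mock filter. Against mock filter alone as control, a comparison chosen after the data were seen, fthl28 in harbour stood at -0.09. Counts of single fthl genes are uncertain, since these genes resemble each other closely.

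A few antioxidant and conjugating enzymes rose in harbour. Of 20 Nrf2 and antioxidant genes 3 rose, namely prdx1, a peroxiredoxin, by 0.84 ± 0.16, txnrd3, a thioredoxin reductase, by 0.35 ± 0.07, and gclc, of glutathione synthesis, by 0.21 ± 0.05. Adjusted over the list alone 8 were higher and 1 lower (adjusted p = 0.083 with an estimated correlation). The glucuronidation gene ugt1b1 and the sulfotransferase sult1st1 rose by 0.63 ± 0.13 and 0.62 ± 0.15, which made 2 of 17 phase II genes (adjusted p = 0.9 with an estimated correlation). Among 20 heat shock genes the chaperones hspa4a (0.90 ± 0.20), hsp90aa1.2 (0.82 ± 0.20) and hspd1 (0.48 ± 0.11) rose and 0 fell. Adjusted over the list alone 11 were higher (adjusted p = 0.119 with an estimated correlation).

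Markers of organs moved in both directions in harbour. Of 22 genes of the exocrine pancreas 4 rose, among them the elastase cela1.4 (0.75 ± 0.12), the amylase amy2al2 (0.65 ± 0.14) and the chymotrypsin-like ctrl (0.49 ± 0.11); adjusted over the list alone 16 were higher (adjusted p = 0.119 with an estimated correlation). The globins hbbe1.1 and hbae3 of red blood cells rose by 0.88 ± 0.22 and 0.63 ± 0.16, 2 of 18 erythroid genes (adjusted p = 0.216 with an estimated correlation). The erythroid list mean against vehicle was 0.61, 0.89 and 1.14 in log2 in the series 35 pools, harbour 1, 2 and 6. It was 0.04, 0.14, -0.11 and -0.02 in harbour 3, 4, 5 and 7. In series 37 alone 0 of 18 were higher in filter 36 and 2 in filter 38. The epidermal keratins krt93 (-0.70 ± 0.15), krt4 (-0.59 ± 0.13) and krt15 (-0.51 ± 0.10) fell, 3 of 24 skin genes, with 8 lower when adjusted over the list alone (adjusted p = 0.083 with an estimated correlation). pomca, the precursor of the pituitary hormone ACTH, rose by 1.25 ± 0.30 and star, which moves cholesterol into mitochondria for steroid synthesis, by 0.62 ± 0.14.

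The largest rises in harbour were in genes scarcely expressed in vehicle. jac9 (ENSDARG00000074983), a jacalin-like lectin, rose by 7.47 ± 1.5, its relatives jac8 and jac1 by 5.38 ± 1.28 and 2.75 ± 0.70, the P450 cyp2k6 by 2.82 ± 0.63 and the pituitary hormone prl by 2.69 ± 0.61. For jac9 vehicle held 0.24 ± 0.238 CPM (SD, n = 6) and harbour 4.2 to 104 CPM (n = 9), and mock filter 1 reached 54.1 CPM. The nuclear receptor gene nr0b2a (-0.98 ± 0.20), the transglutaminase tgm1l2 (-0.93 ± 0.23), the proteoglycan cspg4bb (-0.68 ± 0.16) and the carbonic anhydrase ca15a (-0.59 ± 0.13) were among the genes that fell most. In all, 276 genes changed in harbour (n = 9) against vehicle (n = 6), 193 higher and 83 lower. Within series the counts were 20 (series 35) and 29 (series 37), and without filter 32, 36 or 38 the count was 70, 2608 or 17. Without filter 38, 8 of 39 named calls were kept and 31 did not pass. Leaving out harbour 1, 3, 4, 7, 8 or 9 gave 70, 783, 617, 126, 96 or 106 genes, and leaving out vehicle 1, 2, 4, 5 or 6 gave 132, 138, 108, 86 or 118.

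Of 39 named calls in harbour, 23 were lost when 1 library or another was left out, 19 of them without harbour 1. ahrra, cyp1a, cyp1b1, cyp1c1, cyp1c2, ahr2, fthl28, fthl29, fthl31, mt2, slc30a1a, prdx1, ugt1b1, cela1.4, krt15 and jac9 passed in each of these fits. The calls of jac8, jac1, cyp2k6, prl, pomca, star, hspa4a, hsp90aa1.2, hspd1, hbbe1.1, hbae3, sult1st1, ctrl, txnrd3, krt93, krt4, tgm1l2, cspg4bb and ca15a were lost without harbour 1. Of these, only txnrd3, krt4 and ca15a were lost in that fit alone. The others were lost in further fits as well, and hbbe1.1 and hbae3 were lost without any 1 of the vehicle libraries. amy2al2 was lost without vehicle 4, nr0b2a without vehicle 6, sult6b1 without vehicle 1, 4 or 5, and gclc without these or harbour 7 or 8. The 9 pools come from 3 filters, and with the filter as a random block 35 genes passed, among the named ones ahrra, cyp1a, cyp1b1, cyp1c1, cyp1c2, fthl28, fthl29, fthl31, mt2, prdx1 and cela1.4.

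Road extracts gave the same kind of AhR response. ahrra rose by 2.88 ± 0.34 in log2 (SE, adjusted p = 1.05e-05 in edgeR) and cyp1a by 1.77 ± 0.25 (adjusted p = 0.000188), with 122 ± 105 CPM of cyp1a in road (SD, n = 9) and 33.5 ± 4.52 CPM in vehicle (n = 6). cyp1b1, cyp1c1 and cyp1c2 rose by 1.66 ± 0.20, 0.95 ± 0.11 and 0.74 ± 0.16, and ahr2 by 0.32 ± 0.05. Thus 6 of 15 AhR targets rose and 0 fell; adjusted over the list alone 10 were higher. The set passed (adjusted p = 0.00121 with an estimated correlation).

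Iron and metal genes rose in road too: fthl28 by 2.4 ± 0.25, fthl29 by 2.37 ± 0.30, fthl31 by 1.74 ± 0.20, fthl30 by 1.26 ± 0.21 and mt2 by 1.13 ± 0.15. Of 14 metal response genes 5 rose and 0 fell, with 6 higher and 2 lower when adjusted over the list alone, and the set passed (adjusted p = 0.00216 with an estimated correlation). The mean of this list also lay above vehicle in mock filter 1, 2 and 3, by 0.51, 0.38 and 0.3 in log2. The set test against vehicle thus does not part road air from the filter and its extraction. The peroxiredoxin prdx1 rose by 1.06 ± 0.16 and gclc by 0.23 ± 0.05, 2 of 20 antioxidant genes. Adjusted over the list alone 13 were higher, and the set passed (adjusted p = 0.0351 with an estimated correlation). ugt1b1 rose by 0.60 ± 0.13. Of 20 heat shock genes 0 passed in edgeR over all genes tested, and adjusted over the list alone 12 were higher (adjusted p = 0.142 with an estimated correlation).

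In road the lectin jac9 rose by 6.84 ± 1.5, the protease prss60.3 by 1.54 ± 0.33 and the fibrocystin-like pkhd1l1.1 by 1.18 ± 0.21. The nuclear receptor nr0b2a fell by 0.85, the proteoglycan cspg4bb by 0.72, the epidermal keratin krt15 by 0.55, the adhesion gene ceacam1 by 0.55, the eye and forebrain regulator otx2b by 0.48 and the muscle actin acta1a by 0.40. In all, 91 genes changed in road (n = 9) against vehicle (n = 6), 67 higher and 24 lower. Within series the counts were 3 (series 35) and 20 (series 37), and without filter 28 it was 1821. Without filter 26 the count fell, and 11 of 23 named calls were kept while 12 did not pass. Leaving out road 3, 4, 5 or 8 gave 53, 48, 59 or 138 genes, and leaving out vehicle 4, 5 or 6 gave 55, 44 or 39. Of 23 named calls 10 were lost in such fits: cyp1c2, jac9, prss60.3, nr0b2a, cspg4bb, otx2b and acta1a without road 3, gclc and ceacam1 without vehicle 5, and ugt1b1 without vehicle 4. Those lost without road 3 were each lost in other fits too, such as cyp1c2 without vehicle 1, 2, 4, 5 or 6 or road 2, 4 or 9. With the filter as a random block 26 genes passed, and cyp1c2, gclc, ugt1b1, jac9, prss60.3, nr0b2a, cspg4bb, krt15, ceacam1, otx2b and acta1a did not. Against mock filter alone as control, a comparison chosen after the data were seen, prss60.3 stood at -0.22 and acta1a at 0.14.

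**Figure D2:**
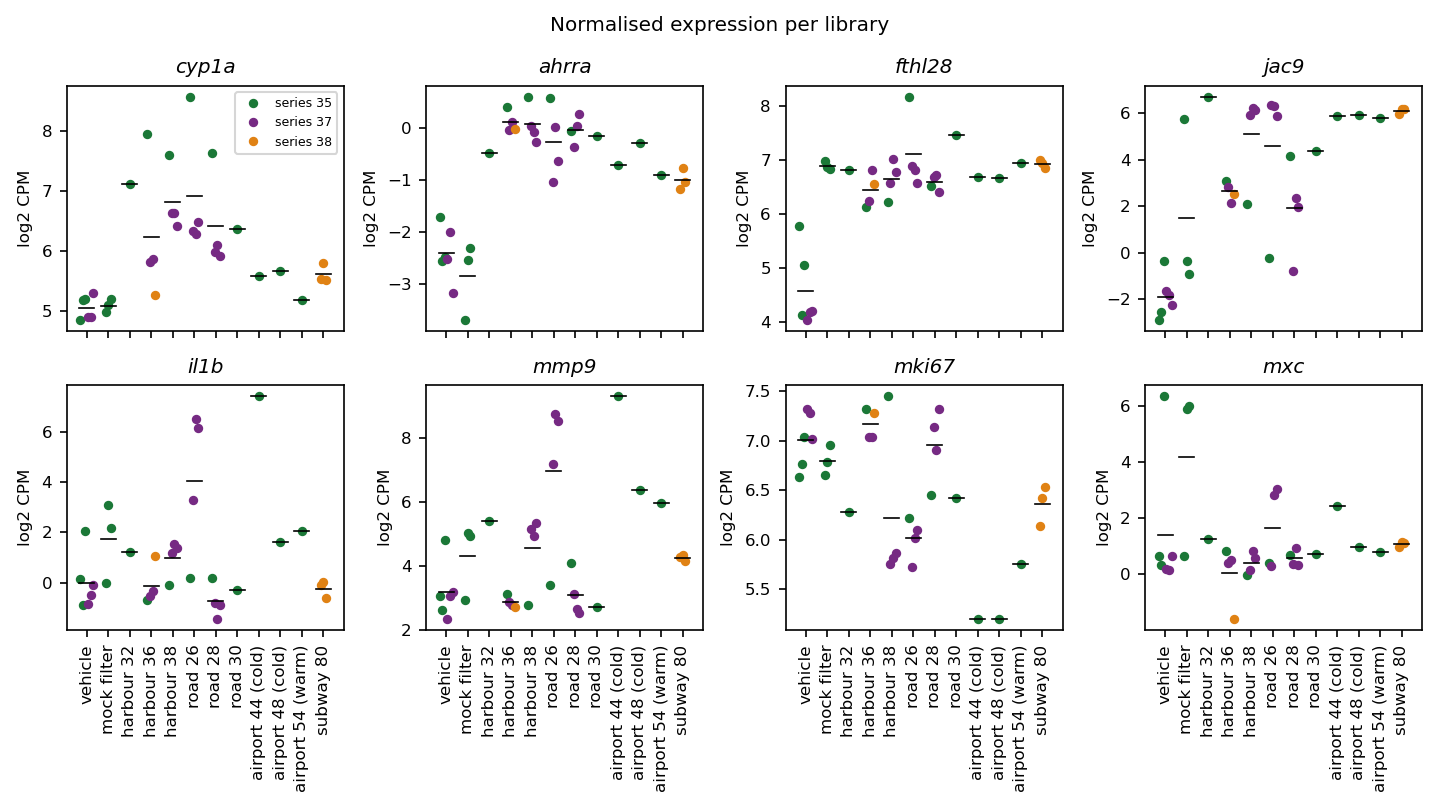
Normalised expression (y axis, log2 CPM) of 8 genes in each of the 33 libraries, by control group or filter (x axis), with colour for the library series and a bar for the mean of each group. cyp1a averages 33.5 CPM in vehicle and is at 82.8 to 378 CPM in the series 35 pools of harbour and road, while il1b is highest in airport filter 44 at 169 CPM.

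Harbour was set against road to ask whether 2 sites of 1 city and season differ. 0 genes passed in edgeR and 863 had an unadjusted p under 0.05; DESeq2 called 1. cyp1a differed by 0.01 ± 0.22 in log2 (SE, harbour minus road), ahrra by 0.16 ± 0.23, cyp1b1 by 0.06 ± 0.17 and fthl28 by -0.35 ± 0.20. Of the genes changed against vehicle, 67 were shared by harbour and road in the same direction, where independent lists would share 0.67. Simulated unchanged groups had 0 harbour and 0.05 road calls on average, so their shared count of 0 sets no measure for it. With the vehicle libraries split so that the sites shared no control, 13 genes were shared in each of both splits, where independent lists would share 0.02. Fold changes correlated at 0.788 across genes, and at 0.606 in simulated unchanged groups that share the vehicle libraries, and at 0.231 and 0.237 with split vehicle libraries. The covariance was 0.0822 against 0.0295 in simulation, a difference of 0.0527, and 0.0344 and 0.0351 with split vehicle libraries. Genes are not independent replicates.

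Airport extracts changed far more genes. Cytokines and tissue-degrading enzymes were among the large rises: il11a by 8.48 ± 1.58 in log2 (SE, adjusted p = 0.000269 in edgeR), il1b (ENSDARG00000098700) by 6.37 ± 1.47 (adjusted p = 0.00163), and the matrix metalloproteinases mmp9 and mmp13a by 4.93 ± 1.15 and 4.92 ± 1.01. For il1b the pools had 169 CPM (filter 44), 2.99 CPM (filter 48) and 4.12 CPM (filter 54), and vehicle 1.25 ± 1.38 CPM (SD, n = 6). Without filter 44, il1b, mmp9, scpp8 and nppb no longer passed. The prostaglandin enzyme ptgs2b rose by 2.35 ± 0.44, the cytokine signal suppressor socs3a by 2.14 ± 0.31 and the NF-kB inhibitor nfkbiaa by 1.33 ± 0.24. Of 24 inflammation genes 17 rose and 0 fell, with 19 higher when adjusted over the list alone (adjusted p = 0.348 with an estimated correlation). In series 35 alone 11 of 22 were higher.

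Protein folding and stress genes rose together in airport. Of 20 genes of the unfolded protein response 19 rose and 0 fell, among them the chaperone partner dnajb9b (2.68 ± 0.37), creld2 (1.69 ± 0.30) and asns (1.46 ± 0.22). Adjusted over the list alone all 20 were higher (adjusted p = 0.279 with an estimated correlation). Of 20 heat shock genes 14 rose and 0 fell, with hsp90aa1.2 and hspa4a each at 1.51 (SE 0.26 and 0.27), and 15 were higher when adjusted over the list alone (adjusted p = 0.294 with an estimated correlation). Of 21 genes of the glucocorticoid and energy stress list 15 rose and 0 fell, with pomca at 2.03 ± 0.38 and cebpd at 1.17 ± 0.16 (adjusted p = 0.294 with an estimated correlation). In series 35 alone 14 unfolded protein response, 13 heat shock, 10 glucocorticoid list and 6 antioxidant genes were higher. Of 20 antioxidant genes 10 rose, with prdx1 at 1.47 ± 0.21, and 2 fell (adjusted p = 0.372 with an estimated correlation). The ferritin genes fthl28 and fthl31 rose by 1.86 ± 0.30 and 1.80 ± 0.25, yet against mock filter alone fthl28 stood at -0.13 and fthl31 at 0.71, and neither passed.

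Genes of cell division, translation and tissue structure fell in airport. Of 31 cell cycle genes 29 fell and 0 rose, such as the mitotic kinase aurkb (-1.54 ± 0.32) and ccne2 of S phase entry (-1.40 ± 0.29); adjusted over the list alone 29 were lower (adjusted p = 0.336 with an estimated correlation). The proliferation marker mki67 was at 42.4 ± 9.77 CPM in airport (SD, n = 3) and 131 ± 24.2 CPM in vehicle (n = 6). Of 30 ribosomal protein genes 27 fell and 0 rose, with rpl3 at -0.53 ± 0.12 (adjusted p = 0.336 with an estimated correlation). In series 35 alone 29 cell cycle genes and 9 ribosomal protein genes were lower. Of 26 bone, cartilage and matrix genes 20 fell and 2 rose, among the former lum (-1.60 ± 0.20), col9a1a (-1.25 ± 0.17) and col2a1a (-1.13 ± 0.15) (adjusted p = 0.279 with an estimated correlation).

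Genes of the eye, blood and pancreas were in part lower in airport, and skin genes moved both ways. Of 35 lens crystallin and lens membrane genes 27 fell and 0 rose, with the lens water channel mipa at -1.14 ± 0.21 and crybb1l2 at -0.64 ± 0.14 (adjusted p = 0.296 with an estimated correlation). Of 43 phototransduction genes 20 fell and 3 rose, with the red cone opsins opn1lw1 and opn1lw2 at -2.01 ± 0.41 and -1.27 ± 0.21 (adjusted p = 0.336 with an estimated correlation). Of 18 erythroid genes 10 fell and 0 rose, with hbbe1.3 at -1.36 ± 0.31 (adjusted p = 0.336 with an estimated correlation), and of 22 pancreatic genes 10 fell and 1 rose, with pla2g1b at -1.06 ± 0.22 (adjusted p = 0.404 with an estimated correlation). In series 35 alone 17 lens, 17 phototransduction, 5 erythroid and 6 pancreatic genes were lower. Of 24 skin genes 13 fell and 8 rose; the keratins krtt1c19e and krt91 fell by 2.56 and 1.23 (adjusted p = 0.32 with an estimated correlation). col7a1, a collagen that anchors the epidermis, fell by 2.69 and the apolipoprotein B gene apobb.2 by 3.36. gfap of glia fell by 0.86, rag2 of developing lymphocytes by 1.57 and the deiodinase dio1 by 1.24.

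In airport, AhR targets gave a mixed picture in the fit of all libraries. ahrra rose by 2.04 ± 0.44, cyp1c2 by 1.03 ± 0.22, ahr2 by 0.37 ± 0.07 and nfe2l2b by 0.62 ± 0.20, while ahr1b fell by 0.42. cyp1a did not pass at -0.20 ± 0.35 (45.2 ± 7.64 CPM, SD, n = 3), nor did cyp1b1 at -0.07 ± 0.28 or cyp1c1 at 0.00 ± 0.14. In series 35 alone cyp1a stood at 0.40 (adjusted p = 0.491 in edgeR). Thus 4 of 15 rose and 1 fell in the fit of all libraries, also when adjusted over the list alone (adjusted p = 0.388 with an estimated correlation). With series 35 libraries alone 4 of 15 were higher and 0 lower, with a median log2 fold change of 0.33. The direction of the list in airport thus depends in part on how series is handled. The covariate gives all groups 1 series shift. The 6 AhR members called in both harbour and road averaged 2.8 log2 CPM in series 35 vehicle and 2.84 in series 37 vehicle. In filter 36 they stood at 4.68 and 3.78, and filters 26, 28 and 38 were higher in series 35 too. The fit of all libraries thus sets airport, all in series 35, against a vehicle level raised by a shift that vehicle did not show. Why exposed pools differ by series was not tested. The lectins jac9 and jac8 rose by 8.39 ± 1.65 and 7.12 ± 1.44, prl by 4.49 ± 0.72, the calcium-binding scpp8 by 4.41 ± 0.96 (not passing without filter 44), the AP-1 gene fosl1a by 4.19 ± 0.87 and the complement gene c7b by 3.68 ± 0.81. The fibrinogen chain fgb, the atrial myosin myh6 and the natriuretic peptide nppb rose by 1.44 ± 0.28, 1.48 ± 0.27 and 1.98 ± 0.60 (nppb not without filter 44), and the glutathione transferase gstt1b fell by 1.24.

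In all, 7663 genes changed in airport (n = 3) against vehicle (n = 6), 3860 higher and 3803 lower, and 900 and 938 of these had a log2 fold change of at least 1. With series 35 libraries alone 4107 passed, and with mock filter as the only control, both chosen after the data were seen, 4028. Against mock filter alone jac9, jac8, il1b, mmp9, scpp8, c7b, socs3a, nfkbiaa, creld2, hsp90aa1.2, hspa4a, apobb.2, opn1lw1, cyp1c2, fthl28 and fthl31 did not pass. Adjusted over the list alone, 17 glucocorticoid list and 10 antioxidant genes were higher (2 antioxidant lower), and 29 ribosomal, 20 bone and matrix (2 higher), 32 lens, 21 phototransduction (3 higher), 10 erythroid, 10 pancreatic (1 higher) and 13 skin genes (9 higher) were lower. No list passed as a set with an estimated correlation in this comparison, and 19 of 33 passed with a preset one.

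**Figure D3:**
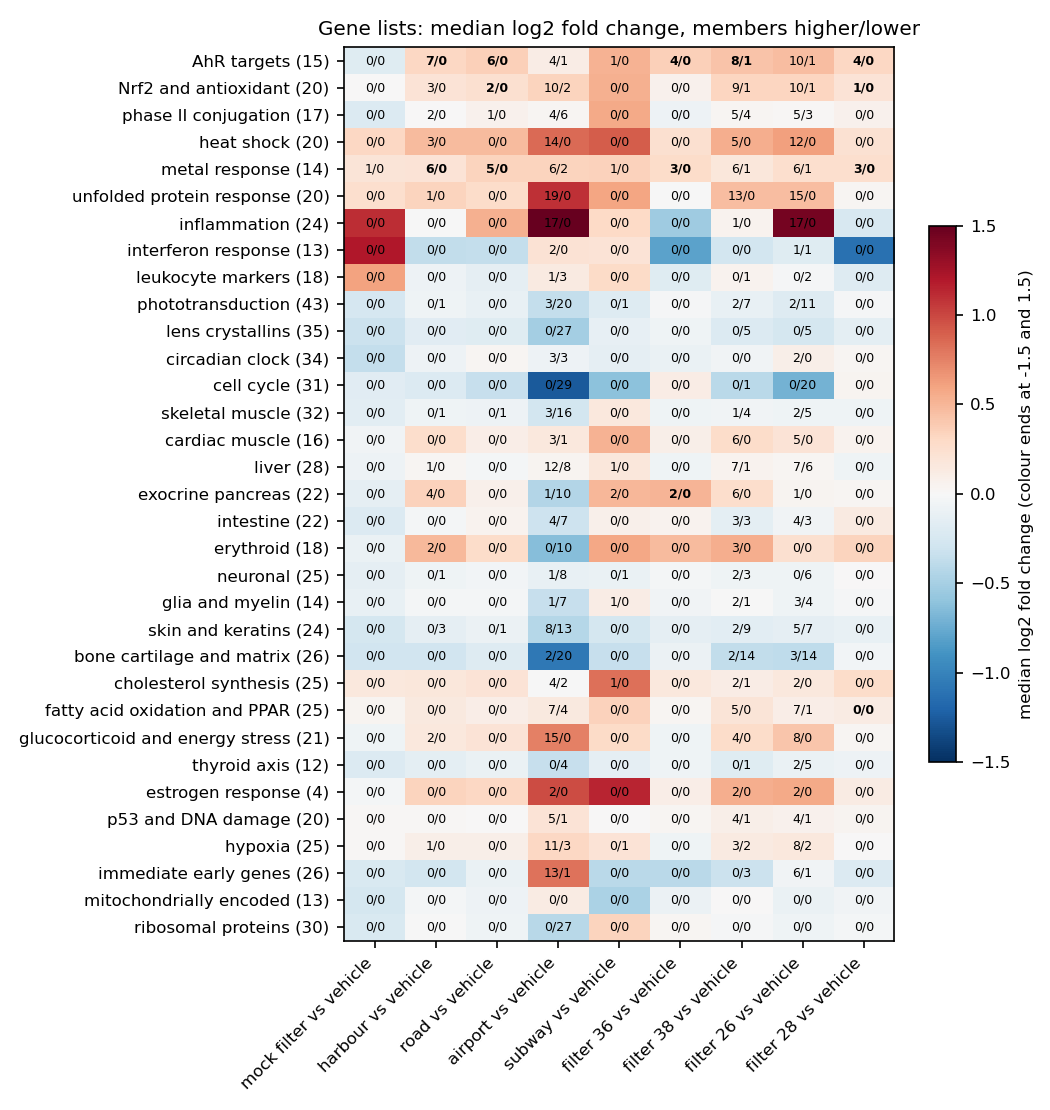
Median log2 fold change (colour) of the 33 gene lists (y axis, number of genes tested in brackets) in 9 comparisons with vehicle (x axis), with the members higher and lower past adjusted p 0.05 written in each cell and in bold where the set test passed with an estimated correlation. In airport 29 of 31 cell cycle genes are lower and 19 of 20 unfolded protein response genes higher, while the AhR list is bold for harbour and road.

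Airport was then compared directly with harbour and road. cyp1a was lower in airport by a log2 difference of -1.98 ± 0.34 (SE, adjusted p = 0.000497 in edgeR), cyp1b1 by -1.77 ± 0.26 and cyp1c1 by -1.02 ± 0.14. sult6b1 was at -0.36 ± 0.13 (adjusted p = 0.049); without the series covariate it stood at 0.11, and without airport cold 1 among other libraries it did not pass. ahrra did not pass at -0.92 ± 0.36 (adjusted p = 0.0596). 4 of 15 AhR targets were lower and 0 higher, and 5 were lower when adjusted over the list alone (adjusted p = 0.35 with an estimated correlation). In series 35, where all 3 sites have 3 pools, cyp1a was 193 ± 54.7 CPM in harbour, 220 ± 149 CPM in road and 45.2 ± 7.64 CPM in airport (SD, n = 3 each).

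The inflammatory genes il1b and mmp9 were higher in airport than in harbour and road by 4.80 ± 1.39 and 3.15 ± 1.08, the lectin itln3 by 5.02 ± 1.27 and the acute-phase regulator cebpb by 2.27 ± 0.43. Of 24 inflammation genes 17 were higher and 0 lower, with 19 higher when adjusted over the list alone (adjusted p = 0.35 with an estimated correlation), and of 20 unfolded protein response genes 13 were higher and 0 lower, with 16 higher when adjusted over the list alone (adjusted p = 0.22 with an estimated correlation). Of 31 cell cycle genes 25 were lower, and so were 25 of 30 ribosomal protein genes, 14 of 22 pancreatic and 12 of 18 erythroid genes (adjusted p = 0.195 with an estimated correlation for both of the last). In all, 4998 genes differed, 2419 higher and 2579 lower in airport. The count was 2610 without airport cold 1, the pool of filter 44, and without it il1b, mmp9 and itln3 no longer passed. The call of mmp9 was also lost without harbour 2 or 6 or road 1, 5 or 9.

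Subway extract (n = 3) changed 92 genes against vehicle (n = 6), 50 higher and 42 lower. The ferritin gene fthl31 rose by 2.45 ± 0.50 in log2 (SE, adjusted p = 0.028 in edgeR), growth hormone gh1 by 1.81 ± 0.36 and the apolipoprotein B gene apobb.1 by 1.11 ± 0.22. These 3 of the 15 named genes also passed without the series covariate. The P450 cyp1c1 rose by 1.39 ± 0.26, the only one of 15 AhR targets to pass over all genes tested, and 6 were higher when adjusted over the list alone (adjusted p = 0.215 with an estimated correlation). cyp1a stood at 2.14 ± 0.64 (adjusted p = 0.082), with 49.2 ± 5.57 CPM in subway (SD) and 33.5 ± 4.52 CPM in vehicle. jac9 had 69.7 ± 6.63 CPM in subway and 0.24 ± 0.238 CPM in vehicle, and did not pass at 11.08 ± 3.5 (adjusted p = 0.092).

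Pancreatic enzymes in subway included cela1.2 (2.39 ± 0.55), cela1.4 (1.56 ± 0.30) and ctrl (1.2 ± 0.27), which rose; 2 of 22 pancreatic list genes rose, with 9 higher and 1 lower when adjusted over the list alone (adjusted p = 0.371 with an estimated correlation). The muscle gene csrp3 rose by 1.87 ± 0.40, idi1 of sterol synthesis by 1.05 ± 0.23 and the glial s100b by 1.19 ± 0.25. The photoreceptor regulator crx (-1.05 ± 0.20), the neuronal RNA-binding elavl3 (-0.75 ± 0.13), the carbonic anhydrase ca9 (-2.01 ± 0.38), the kinase sik1 (-1.53 ± 0.36) and the proteoglycan cspg4bb (-1.70 ± 0.36) fell. All subway pools are in series 38, where the only other library is harbour 5, so these values rest on that library. Without the series covariate 56 genes passed, of which 11 were among the 92, and without subway 1, 2 or 3 the count was 27, 0 or 1, and none of the 15 named calls passed without subway 2 or 3. Without vehicle 2, 3, 4 or 5 it was 210, 340, 32 or 36. In a fit of subway and vehicle alone ctrl stood at -0.04 and sik1 at 0.06.

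Filters of the same site were compared to ask how far single air samples differ. Road filter 26 differed from road filter 28 (n = 4 each) in 1752 genes, 1106 higher and 646 lower in filter 26. il1b was higher in filter 26 by 6.11 ± 0.96 in log2 (SE, adjusted p = 0.00167 in edgeR), mmp9 by 4.66 ± 0.79, mmp13a by 3.78 ± 0.55, the neutrophil chemokines cxcl8a and cxcl18b by 3.73 ± 0.73 and 3.68 ± 0.82, the stress regulators atf3 and cebpb by 1.72 ± 0.35 and 1.5 ± 0.32 and the junction gene cldni by 0.95 ± 0.18. The mitotic checkpoint kinase bub1 was lower by a log2 difference of -1.02 ± 0.25, mki67 by -0.99 ± 0.26 and apobb.2 by -2.41 ± 0.59. Of 24 inflammation genes 16 were higher and 0 lower, with 20 higher when adjusted over the list alone (adjusted p = 0.343 with an estimated correlation). Of 18 leukocyte markers 0 passed in edgeR, and in series 37 alone 8 were higher and 2 lower. Of 20 unfolded protein response genes 9 were higher (adjusted p = 0.337), and of 31 cell cycle genes 13 were lower (adjusted p = 0.454, both with an estimated correlation). Of the 15 AhR targets 0 passed in edgeR, with cyp1a at 0.56 ± 0.28 and ahrra at -0.24 ± 0.33. With the replicate number as a block, fitted to the compared libraries alone, 0 of the 25 named calls of the blocked comparisons passed, those of filters 26 and 28 included. Their same-numbered pools correlated at only 0.059 to 0.2, so this block is itself uncertain. Leaving out 1 of road 1 to 8 gave 3108, 562, 598, 450, 2803, 533, 538 and 411 genes in that order, and the calls of bub1, mki67 and apobb.2 were lost without road 2, 3, 4 or 7. The higher il1b of filter 26 lay in its series 37 pools, at 57.3 ± 42.3 CPM (SD, n = 3), with 1.07 CPM in its series 35 pool.

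Harbour filters 36 and 38 (n = 4 each) differed in 715 genes, 204 higher and 511 lower in filter 36. The lectin jac1 was lower by -2.47 ± 0.67, the complement gene c7b by -2.42 ± 0.60, the protease inhibitor timp2b by -1.93 ± 0.54 and the estrogen receptor esr2b by -1.06 ± 0.27. Of 20 unfolded protein response genes 4 were lower and 0 higher, among them pdia6 (-0.59 ± 0.15), atf4a (-0.39 ± 0.10) and xbp1 (-0.27 ± 0.07), and 8 were lower when adjusted over the list alone (adjusted p = 0.385 with an estimated correlation). The actin regulator abi1b (0.88 ± 0.15), the taurine transporter slc6a6a (0.92 ± 0.23), the lens filament gene BFSP1 (0.86 ± 0.16) and the glutamate transporter slc17a6a (0.76 ± 0.12) were higher in filter 36. Of the 15 AhR targets 0 passed in edgeR, with cyp1a at -0.32 ± 0.31. With the replicate number as a block and only the pools of these filters in the fit, 1 gene passed. In that fit 0 of 33 lists passed as a set, with a smallest adjusted p of 0.414 in camera. The same pools fitted without the block gave 0 genes. Without harbour 2, 3, 7, 8 or 9 the count was 110, 1, 2, 1 or 4, with all 11 named calls lost without harbour 3, and without harbour 6, the series 35 pool of filter 38, it was 3412.

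Against vehicle, filter 36 changed 15 genes and filter 28 changed 20, while filter 38 changed 2369 and filter 26 changed 3838. In filter 36 ahrra rose by 3.20 ± 0.41 in log2 (SE, adjusted p = 0.000451 in edgeR), cyp1a by 1.64 ± 0.27, cyp1b1 by 1.54 ± 0.22, cyp1c1 by 1.05 ± 0.13, fthl28 by 1.88 ± 0.30 and mt2 by 0.96 ± 0.19. In filter 28 ahrra, cyp1a, cyp1b1, cyp1c1, fthl28 and mt2 rose by 3.07 ± 0.39, 1.56 ± 0.25, 1.52 ± 0.20, 0.99 ± 0.12, 2.06 ± 0.28 and 1.04 ± 0.17, and prdx1 by 0.73 ± 0.12. In filter 36 the calls of cyp1a and cyp1b1 were lost without harbour 2, its series 35 pool, that of fthl28 without harbour 4, and that of mt2 without harbour 3 or 4 or vehicle 3, 4, 5 or 6. In filter 28 those of cyp1a and mt2 were lost without road 5, its series 35 pool. cyp1a rose by 1.96 ± 0.26 in filter 38 and by 2.12 ± 0.26 in filter 26. Filter 26 also raised il11a by 5.59 ± 0.98, il1b by 4.89 ± 0.89, mmp9 by 4.44 ± 0.73, hsp70.1 by 3.27 ± 0.80, timp2b by 3.18 ± 0.46 and prdx1 by 1.33 ± 0.11, and lowered apobb.2 by a log2 difference of -2.60 ± 0.56 and the liver glycoprotein ahsg1 by -1.38 ± 0.33. Filter 38 raised jac9 by 7.69 ± 1.43, prl by 3.05 ± 0.54, cyp2k6 by 2.96 ± 0.55, the vitellogenin vtg7 by 2.48 ± 0.54 and creld2 by 0.95 ± 0.22, and lowered ahsg1 by -1.57 ± 0.34 and krt93 by -0.88 ± 0.15.

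The AhR list passed as a set in filter 38, with 8 of 15 higher and 1 lower (adjusted p = 0.0418 with an estimated correlation), and in filter 26 10 were higher and 1 lower (adjusted p = 0.0586). It also passed in filter 36 (4 higher, 0 lower, adjusted p = 0.0034) and in filter 28 (4 higher, 0 lower, adjusted p = 0.000339). The set of 14 metal response genes passed in filter 36 (3 higher, 5 when adjusted over the list alone, adjusted p = 0.00365) and in filter 28 (3 higher, 8 higher and 1 lower over the list alone, adjusted p = 0.000339). Its mean also lay 0.51, 0.38 and 0.3 in log2 above vehicle in mock filter 1, 2 and 3, so the sampled air is not parted from the filter here. Sets of pancreatic genes in filter 36 (2 of 22 higher, 17 over the list alone, adjusted p = 0.00595) and of antioxidant genes in filter 28 (1 of 20 higher, 5 over the list alone, adjusted p = 0.00526) passed as well. Fatty acid oxidation genes passed as a set in filter 28 with 0 of 25 members past the threshold in edgeR or over the list alone (adjusted p = 0.019), and all these p-values have an estimated correlation. In series 37 alone, chosen after the data were seen, the counts against vehicle were 45 for filter 36, 38 for filter 28, 6583 for filter 38 and 7355 for filter 26. Without the series covariate 7 genes passed for filter 36 and 9 for filter 28. Leaving out harbour 2 or 4 gave 6 genes each for filter 36, and leaving out road 5 gave 7 for filter 28. For filter 38 the count was 4688 without harbour 6 and 961 to 1228 without harbour 7, 8 or 9, and 1315 or 1210 without vehicle 4 or 5. For filter 26 it was 2159 to 2339 without road 2, 3 or 4, and 2536 or 2528 without vehicle 4 or 5. In the 4 filters cyp1a was higher in the single series 35 pool than in the series 37 pools: 378 against 82.5 ± 5.83 CPM in filter 26 (SD, n = 3), 198 against 64 ± 3.99 CPM in filter 28 (n = 3), 247 against 57.6 ± 1.41 CPM in filter 36 (n = 2) and 194 against 94.6 ± 8.5 CPM in filter 38 (n = 3). Vehicle had 34.1 ± 4.49 CPM of cyp1a in series 35 and 32.9 ± 5.45 CPM in series 37 (n = 3 each). The proliferation marker mki67 was also higher in series 35 in filter 38, with 175 CPM in its series 35 pool and 56.3 ± 2.43 CPM in its series 37 pools.

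**Figure D4:**
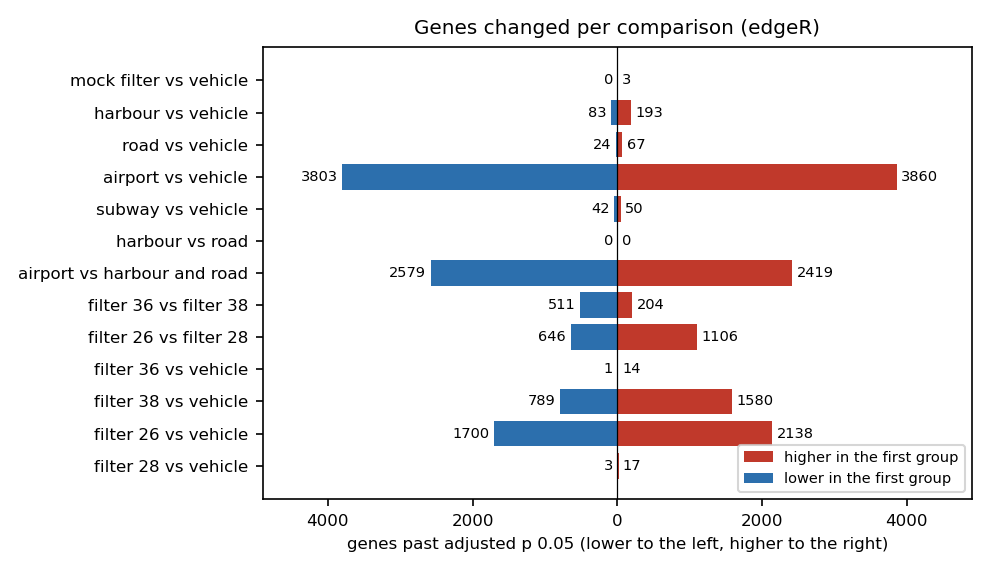
Genes higher (right of 0) and lower (left of 0) past adjusted p 0.05 in edgeR in each of the 13 comparisons (y axis), with the number of genes on the x axis and beside each bar. Airport against vehicle has 3860 higher and 3803 lower, and harbour against road has 0.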

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

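The tests of extract dose, time of day, uniquely mapped reads and interferon genes here were chosen after the results they weigh were seen; the tests of depth, unmapped reads and shared response were planned.

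The antiviral gene mxc was at 6.34 log2 CPM in vehicle 3, far from 0.16 to 0.65 in the other 5 vehicle libraries. In vehicle 3, mmp9 was at 4.8 (others 2.34 to 3.18) and il1b at 2.04 (others -0.88 to 0.15). mxc was at -1.6 in harbour 5 and at -0.03 to 1.25 in the other 8 harbour libraries. Chance singles out about 1 in 20 groups, or 3.5 of the 69 compared here, and 4 were found.

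Interferon genes were high in vehicle 3, mock filter 2 and mock filter 3, a set of libraries defined from these values. Vehicle 3 had no mock filter extract, so an effect of that extract does not account for this pool. Its list mean was 1.61 higher in log2 than that of mock filter 1, with an SD of 0.15 among the other vehicle libraries. The sign of this difference follows from how the 3 were picked. Mock filter 1 also carries the title number 2, and mock filter 2 and 3 the number 3. An effect of the extract on mock filter 2 and 3 therefore stays open. That 0 of the 12 other series 35 libraries reached the lowest of the 3 follows from how the 3 were picked, so an effect of library series 35 on some pools cannot be told apart. To weigh more leukocytes in the pools, the interferon list (2.04 in log2) was set against the leukocyte list (0.89), a difference of 1.14 ± 0.4 (SE over list members, not pools). The 3 libraries were picked by their interferon values, which favours this difference. That more leukocytes would raise both lists alike was assumed and not tested. More leukocytes therefore stay open as the whole cause or a part of it. An infection of some embryos or a shared clutch was not tested and stays open.

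Filters 36 and 38 differed in 715 genes and filters 26 and 28 in 1752, and airport differed from harbour and road in 4998. For airport the differences in cyp1a, cyp1b1 and cyp1c1 were -1.98, -1.77 and -1.02 in log2. Each is a difference between groups past the threshold of a test. With a replicate block, which used only the pools compared, 1 gene was left for filters 36 and 38 and 3 for filters 26 and 28. In a fit of filters 36 and 38 alone without the block 0 passed (4585 at unadjusted p under 0.05 in the edgeR fit of all libraries, 1417 called by DESeq2). For filters 36 and 38 the smaller count thus came with the smaller fit and not with the block alone.

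The broad response of filters 26 and 38 was seen in their series 37 pools; in the single series 35 pools il1b was at 1.07 CPM for filter 26 and mki67 at 175 CPM for filter 38, against 57.3 and 56.3 CPM in series 37. Not every part of it was missing in series 35. For filter 26 mki67 was at 74.4 CPM in the series 35 pool, 52.5 to 68.3 CPM in the series 37 pools and 99.1 to 131 CPM in series 35 vehicle. Sequencing depth is argued against, since with libraries thinned to the depth of the smallest one at least 88 percent of calls were left. Less extract in the series 35 pool would lower the AhR members there. The 6 members called in both harbour and road stood 0.81 higher there for filter 26 and 0.36 higher for filter 38 (log2 CPM). They also stood 0.45 and 0.91 higher for filters 28 and 36. The difference thus goes with the series in all of these filters and does not measure the dose of a single pool, so less extract cannot be told apart. The clock list lay at most 0.1 in log2 from vehicle of series 37, but with 10 members higher and 2 lower in filter 26 its mean decides nothing, so another time of day cannot be told apart. Exposure batch, with single pools in series 35, stays open along with embryo clutch and a higher or lower dose in the series 35 pools.

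The broad response of the airport filters kept 96.2 percent of its calls after thinning, which argues against sequencing depth. Lower read quality of the airport libraries cannot be told apart from a site effect, since 1 of the 3 had an unmapped share above every other series 35 library and the other 2 did not. Fewer uniquely mapped reads are argued against, since 0 of the 3 lay below the median of the other series 35 libraries. The pool of filter 54 had the shortest insert of all libraries (197.3) and the highest mitochondrial share (8.57 percent), and without it 6940 genes passed. All airport pools are in series 35, so a day or clutch of exposure of their own stays open, as does an effect of the airport air, which the design names.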

How the results depend on the processing

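The settings chosen after the data were seen are mock filter alone as control, series 35 alone for airport, series 37 alone for filters, series 37 and 38 as 1 level, and the fit without vehicle 3, mock filter 2 and mock filter 3. Where a value moved, the cause was not tested unless a sentence names it.

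For mock filter against vehicle (3 genes) DESeq2 called 98, a fit of the compared groups alone 0 and a replicate block 0, with 3022 genes at unadjusted p under 0.05 in edgeR; without vehicle 3, mock filter 2 and mock filter 3 the count was 8. For harbour (276) DESeq2 called 688, a minimum log2 fold change of 1 left 45, the compared groups alone gave 36, no series covariate 95, the equally weighted mean of the filters 2067 and limma voom with the filter as a random block 35. Without filter 32, 36 or 38 the harbour count was 70, 2608 or 17; in series 35 or 37 alone it was 20 or 29, with series 37 and 38 as 1 level 136 and with mock filter alone as control 467. For road (91) DESeq2 called 322, the minimum fold change left 28, vehicle and mock filter together gave 51, the mean of the filters 293 and the random block 26. Without filter 26 or 28 the road count was 22 or 1821, in series 35 or 37 alone 3 or 20, and against mock filter alone 340. Larger counts against mock filter alone did not mean that calls held. Over harbour, road and airport together 49 of 111 named calls were kept there, 58 did not pass and 4 turned.

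For airport (7663) the minimum fold change left 1838, the compared groups alone gave 4088, mock filter alone as control 4028 and series 35 alone 4107; the other settings kept the count within 1.5 times. For subway (92) DESeq2 called 965, the minimum fold change left 48, the compared groups alone gave 2603, no series covariate 56, vehicle and mock filter together 17, series 37 and 38 as 1 level 32, and the fit without vehicle 3, mock filter 2 and mock filter 3 gave 167. Harbour against road (0 in edgeR, 863 at unadjusted p under 0.05) had 1 in DESeq2 and 1 in series 35 alone. Airport against harbour and road (4998) had 875 at the minimum fold change.

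Filters 36 and 38 (715) had 1417 in DESeq2, 401 with no filter on low counts, 87 at the minimum fold change, 0 in a fit of the compared groups alone (4585 at unadjusted p under 0.05 in the fit of all libraries), 1578 with series 37 and 38 as 1 level, 1 with the replicate block that pairs the pools, and 4222 in series 37 alone. Filters 26 and 28 (1752) had 303 at the minimum fold change, 3 with a replicate block, and 6073 in series 37 alone. Against vehicle, filter 36 (15) had 7 without the series covariate and 45 in series 37 alone, filter 28 (20) had 9 and 38, filter 38 (2369) had 6583 and filter 26 (3838) had 7355 in series 37 alone. The set tests passed 5 times with an estimated correlation and 112 times with a preset one over the 7 site comparisons. The overlap of harbour and road (67) was 13 and 13 with split vehicle libraries, where each fit has fewer samples.

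Leaving out 1 library gave 3 to 1047 genes for mock filter, 70 to 783 for harbour, 39 to 138 for road, 5594 to 8036 for airport, 0 to 340 for subway, 0 to 0 for harbour against road and 2610 to 5396 for airport against harbour and road. It gave 1 to 3412 for filters 36 and 38, 411 to 3108 for filters 26 and 28, and against vehicle 6 to 19 for filter 36, 961 to 4688 for filter 38, 2159 to 4762 for filter 26 and 7 to 24 for filter 28.

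Of the values of named genes under all settings, 1859 kept their direction and side of the threshold, 540 kept the direction and did not pass, and 7 turned. With mock filter alone as control, fthl28 was -0.09 in harbour and -0.13 in airport, and prss60.3 was -0.22 and acta1a 0.14 in road. Without the series covariate sult6b1 was 0.11 in airport against harbour and road, and in a fit of the compared groups alone ctrl was -0.04 and sik1 0.06 in subway.

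With libraries thinned to the depth of the smallest one, 221 genes were left for harbour, 81 for road, 7369 for airport, 80 for subway and 4730 for airport against harbour and road. Filters 36 and 38 had 431 of 715 genes left, the lowest share among the comparisons with calls, so depth limits that count most.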

Other observations

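The test of a response shared between airport and filter 26 was planned before its result was seen, no bound was set beforehand for the other filters, and the splits of the samples were planned.

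A hypothesis is that airport extracts and the series 37 pools of road filter 26 and harbour filter 38 evoke 1 general stress response. Fold changes of airport in series 35 and of filter 26 in series 37, which share no library, correlated at 0.643 across 21413 genes. Of 4099 airport calls and 7324 of filter 26, 3160 were shared in the same direction and 17 in opposite directions, where independent lists would share 701.1. For filter 38 the correlation was 0.619, with 2924 shared and 627.7 for independent lists, and for filters 36 and 28 it was 0.134 and 0.186. Of the 45 and 37 calls of filters 36 and 28, 21 and 25 were shared, with 4.3 and 3.5 for independent lists, so sharing beyond those lists was not confined to the broad responses. The proliferation marker mki67 was at -1.42 in airport, -1.25 in filter 26 and -1.40 in filter 38 in log2, and the chaperone partner dnajb9b at 2.38, 1.93 and 1.44. Immediate early genes differed in direction: 14 of 26 were higher and 1 lower in airport, 7 and 11 in filter 26, and 5 and 13 in filter 38. fosab was at 1.83, -0.80 and -1.54 in these, btg2 at 1.52, -0.72 and -1.38, and cebpd at 1.28, 0.14 and -0.09. The controls differed too: the list mean was -0.18, -0.55 and -0.9 in vehicle 1 to 3 (series 35) and 0.2, 0.67 and 0.76 in vehicle 4 to 6 (series 37). Against series 37 vehicle the list median was -0.54 in filter 36 and -0.38 in filter 28, beside -0.3 in filter 26 and -0.53 in filter 38. These genes therefore cannot decide for or against a single response.

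Splits of the same libraries show where chance can be excluded for a count of genes. The splits mix library series and ignore filters, so they address only a chance assignment of single pools. A batch of the airport pools, all in series 35, is not excluded by them. Chance can be excluded in this sense for airport (7663 genes, 1 of 84 splits as large, highest other 2127), airport against harbour and road (4998, 1 of 60, highest other 2215), filter 26 (3838, 1 of 60, highest other 407) and filter 28 (20, 1 of 60, highest other 7). It can also for harbour (276, 2 of 60, highest other 978), road (91, 2 of 60, highest other 3949), filter 36 (15, 2 of 60, highest other 81) and mock filter (3, 3 of 84, highest other 1154), though only against splits that ignore filters and replicate numbers: with the filter as a random block harbour and road had 35 and 26 genes, and mock filter had 0 with a replicate block and 0 in a fit of the compared groups alone (3022 at unadjusted p under 0.05 in the edgeR fit of all libraries, 98 called by DESeq2). For subway (92, 1 of 84, highest other 35) chance is excluded only for splits that mix series 38 pools with vehicle of other series, so site and series stay joined, and without subway 2 or 3 the count was 0 or 1. In harbour, road, filter 36 and mock filter another split called several times the real count, which points to a structure of the samples: for mock filter that split set vehicle 3 with mock filter 2 and 3, and for road it set the series 37 pools of filter 28 with the 6 vehicle libraries. For harbour against road (0 in edgeR, 863 at unadjusted p under 0.05, 1 in DESeq2) the splits decide nothing, since 60 of 60 are as large as 0 by construction; the highest other was 1277. Chance cannot be excluded for filter 26 against 28 (1752, 2 of 35, highest other 2063) and filter 38 (2369, 3 of 60, highest other 3750). The highest split for filter 38 set its 3 series 37 pools with vehicle 3, and that for filter 26 against 28 set the series 35 pool of filter 26 with the series 37 pools of filter 28; within series 37 the counts were 6583 and 6073. For filters 36 and 38 (715, 4 of 35, highest other 3700) it cannot either, though among the 8 splits that part all 4 replicate pairs the real count was the highest, with 389 next; the top split joined the series 35 pool of filter 38 to 3 pools of filter 36, which points to a structure by series, and the blocked count was 1.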
